A study of Mus musculus with 6 samples.

How the data were processed

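Total RNA of sorted ILT3+ and ILT3- CD4+CD25+ T cells was sequenced in 6 samples, 3 per group. Per the labels' protocols, 1 ng of RNA per sample was made into full-length cDNA with SmartSeq V2 chemistry, and barcoded libraries were made with a Nextera XT kit. The cells were enriched on magnetic columns and then sorted by flow cytometry. The build GRCm38 is from the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here, nor is any use of strand.

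The authors deposited 1 table per sample with read counts for 38924 genes, in the same order in all 6. Per the file headers, these hold total and unique counts of reads per gene, exon and intron. In every row total gene reads equal exon plus intron reads, and the expression value equals total exon reads. The deposited RPKM and ratio columns were not used here. The deposited gene and exon lengths were not used in any test. Gene models without an annotated exon number 10609 and hold 2.66% of all reads.

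Total gene reads were chosen before the data were examined as the counts to test, with unique and exon reads as alternatives. They include intronic reads (24.0% to 28.3% per library) and reads that also match elsewhere, so overlapping genes and near-identical copies can share reads. Depth was 9334370 to 13648274 reads per library, so that 3 reads, the floor used for genes without reads, correspond to 0.218 to 0.360 CPM. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 18.3 to 128, genes of at least 20 reads), so each library was counted as 1 sample.

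Groups were compared with edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter (minimum count 10, total 15), a robust quasi-likelihood fit on group alone and Benjamini-Hochberg adjustment at 0.05. CPM values use TMM-scaled library sizes, and SE is the log2 fold change divided by the root of the F statistic. The biological coefficient of variation was 0.427, and 0.318 with a block. Of 597 list symbols 569 were in the files by name, 12 were matched through RefSeq synonyms and 16 were not matched. The 35 lists, fixed before the data were examined, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 3 members were tested (32 lists). They cover Treg core, effector Treg, resting T cell, Th1, Th2, Th17, follicular, co-inhibitory, co-stimulatory, suppressive, homing, cell cycle, cytotoxic, interferon, receptor activation, immediate early, CK2, receptor family, metabolic and sort marker genes, and markers of other cell types and sex. Of these, 19 were called, 18 higher and 1 lower, 7 of the higher ones being lists of other cell types. With an estimated correlation 4 were called (effector Treg, Th17, cell cycle and dendritic cell). The lists share genes, so their calls are not independent. Of tested effector Treg genes 23 of 35 were also in other lists, of mediators of suppression 14 of 17 and of homing receptors 16 of 30. Of the 36 cell cycle genes 0 were. Prdm1, the only called plasma cell gene, is also in the effector Treg list.

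Named genes followed a rule fixed before the data were examined: the sort marker, receptor family and CK2 genes; the 10 largest rises and 10 largest falls among called genes of at least 10 CPM on average whose groups did not overlap, leaving out predicted genes, Rik clones, pseudogenes and receptor segments; up to 4 members of each list by smallest p; and the 2 most abundant members of lists of other cell types. That gave 140 genes, some of which are not reported here. Il10, Actn1, Ccr2, Cd200r1, Csf1r, Batf3, Fscn1, Ciita, H2-Eb1 and further genes of the closing part were named after their values were seen.

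Sample numbers 1 to 3 occur in both groups. Deviations from the group means correlated at 0.40, 0.26 and 0.27 between samples of the same number and each library correlated best with its own number, so the numbers were taken to pair the samples by a rule of over 0.1 in all pairs. ILT3- sample 2 with ILT3+ sample 3 (0.117) and ILT3- sample 3 with ILT3+ sample 2 (0.163) passed the same bound. The rule thus sets number 1 apart but does not by itself tell the numbers 2 and 3 from each other. The pairing comes from the data, and the labels do not state it. All count columns were fitted with and without the block in an exploration before the final run, and the unblocked test on total gene reads, fixed before the data were examined, was kept.

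The tests were tried on simulated counts for the ILT3+ against ILT3- comparison (13694 genes, 200 changed). edgeR recovered 6.00% of 2-fold, 52.0% of 4-fold, 80.0% of 8-fold and 88.0% of 16-fold changes, with 8 of 121 calls false. DESeq2 1.42.0 made 172 calls, 35 of them false. A simulated list of 2-fold changes was called with the preset correlation and by fry, but not with an estimated one. The counts were drawn once from edgeR's own dispersions, with independent genes and no effect of sample number. They may therefore favour edgeR, and they cannot choose between the list tests for correlated genes. Alternatives covered scaling, tool, filter, count column, block, thresholds, list test and each sample left out in turn.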

Results

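RNA was sequenced from CD4+CD25+ T cells, a fraction of mouse CD4+ T cells in which regulatory T cells (Tregs) are abundant. Per the labels, the cells came from the spleen and mesenteric lymph nodes of untreated wild-type mice of both sexes, aged 10 to 16 weeks. They were sorted into cells with (ILT3+) and without (ILT3-) surface ILT3. ILT3 is an inhibitory receptor of the leukocyte immunoglobulin-like family, best known from antigen-presenting cells. The comparison asks how CD4+CD25+ T cells that carry ILT3 differ in gene expression from those that do not. How many of the sorted cells were Tregs was not measured. There were 3 samples per group. Total gene reads were 9334370, 12626163 and 13648274 in ILT3- samples 1, 2 and 3, and 10768217, 11869140 and 11960289 in ILT3+ samples 1, 2 and 3. The labels do not say whether the samples came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

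ILT3+ cells differed from ILT3- cells in a set of genes of which most were higher in ILT3+ cells. Of 13694 tested genes, 316 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 269 higher and 47 lower in ILT3+ cells. Of the 316, 308 differed by at least 2-fold, and in all 316 the CPM values of the groups did not overlap. Over all tested genes 20.2% did not overlap. Chance gives 10% for exchangeable libraries, which libraries paired by number are not. The replicate numbers were taken to pair the samples, which the labels do not state. With the number as a block 932 genes were called, 573 higher and 359 lower, including 313 of the 316. The count fell to 67 without ILT3- sample 2, 31 without ILT3- sample 3, 53 without ILT3+ sample 2 and 57 without ILT3+ sample 3. Samples numbered 1 stood apart from the rest on the second principal component, which held 31.95% of the variance, and mitochondrial ribosomal RNA took 2.96% and 2.27% of their reads against 1.13% to 1.66% in the other 4. Without both of them, a setting chosen after the data were seen, 786 genes were called, 625 higher and 161 lower, with 307 of the 316 among them.

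**Figure D1:**
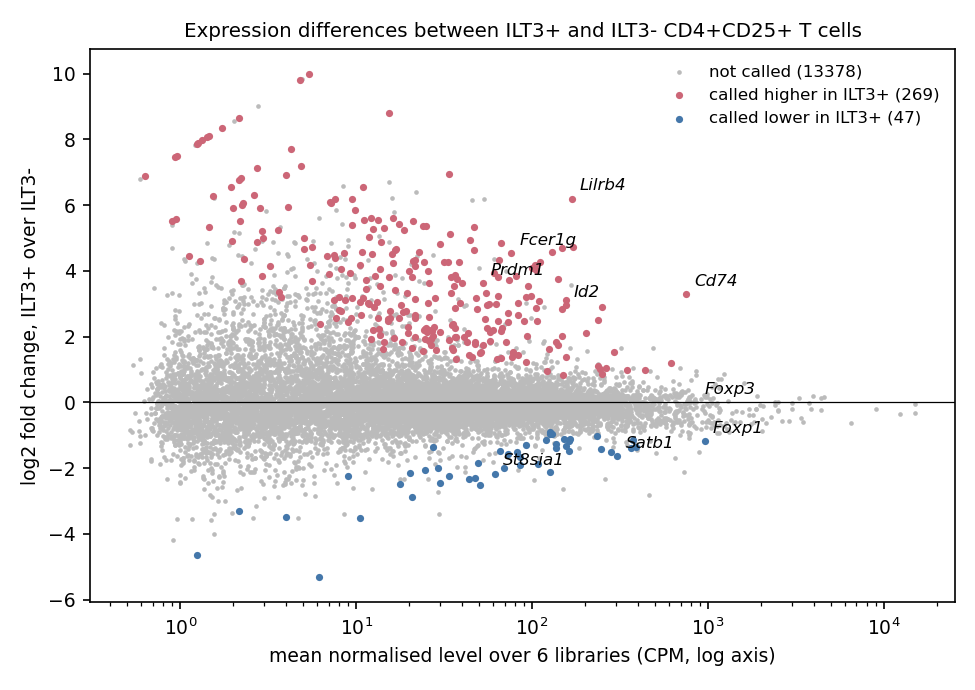
Each point is 1 of 13694 tested genes, placed by its mean level over the 6 libraries (CPM, log axis) and its log2 fold change of ILT3+ over ILT3- cells. Red points are the 269 genes called higher, blue points the 47 called lower; the fold of genes with few reads in ILT3- cells depends on the prior count.

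The gene for ILT3 itself separated the groups. It is named Lilrb4 in the files (GRCm38 chromosome 10, 51480640 to 51496613) and had 4.46 ± 1.29 CPM in ILT3- cells and 332 ± 65.8 CPM in ILT3+ cells (SD, n = 3 each). The log2 fold change was 6.20 (SE 0.31, adjusted p = 0.000327, edgeR). This gene model spans both neighbouring copies of the family that GENCODE M21 lists on the same build, Lilr4b (51480632 to 51486703) and Lilrb4a (51490956 to 51496611), and overlaps the separate row Gp49a (51480632 to 51486316). Reads of the copies can therefore not be assigned with certainty, and 57.6% of the reads of Lilrb4 were counted in introns. Gp49a was 17.4 ± 8.71 CPM in ILT3+ and 0.555 ± 0.494 CPM in ILT3- cells (SD, n = 3, adjusted p = 0.0545, with the block 0.0295). Of the 17 genes in the list of the leukocyte immunoglobulin-like receptor family, 8 were in the files and 2 had enough reads, too few for a list test.

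Foxp3, Il2ra and Cd4 did not differ detectably, while 3 genes of the Treg core list did. Foxp3, the lineage-defining transcription factor, was at 862 ± 233 CPM in ILT3- and 861 ± 127 CPM in ILT3+ cells (SD, n = 3, log2 fold change 0.00, SE 0.24, adjusted p = 0.999). Only 19.0% of its reads were uniquely placed, and its model overlaps 3 others. Il2ra, which encodes CD25, had a log2 fold change of 0.31 (SE 0.36, adjusted p = 0.800) and Cd4 one of 0.42 (SE 0.26, adjusted p = 0.574). Of the 23 tested genes of the Treg core list, 2 were higher and 1 was lower, and 3 and 1 adjusted over the list alone. With the block 6 were higher and 4 lower. The higher genes were Cd83 and Ebi3, a subunit of IL-35 (log2 fold changes 0.87 and 2.26, adjusted p = 0.0341 and 0.00980), and the lower one was Ecm1 (-1.01, adjusted p = 0.0496). Over 19 alternatives the call of Ebi3 was lost in 3, that of Cd83 in 8 and that of Ecm1 in 10. Those of Cd83 and Ecm1 were lost whichever library was left out. The list as a whole was not called by camera (adjusted p = 0.436). Within the sort marker list only Lilrb4 of 6 genes was called, and the list's call (adjusted p = 0.0116) was lost with an estimated correlation (adjusted p = 0.253) and without ILT3- sample 2 (adjusted p = 0.0786).

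Genes of effector Tregs rose and genes of resting lymphoid T cells fell. Of 35 tested effector Treg genes 16 were higher and none lower (24 higher adjusted over the list alone), with a median log2 fold change of 1.65 and an adjusted p of 6.03e-20 in camera, and adjusted p = 0.0264 with an estimated correlation. Prdm1, which encodes the transcription factor Blimp-1, rose from 7.81 ± 0.836 to 97.0 ± 8.02 CPM (SD, n = 3, adjusted p = 0.000435), and Id2 from 35.5 ± 6.61 to 275 ± 9.82 CPM (adjusted p = 0.000906). Klrg1, a receptor of terminally differentiated lymphocytes, rose by 3.12 on the log2 scale (SE 0.42, adjusted p = 0.0127), and S100a4, Maf and Icos by 3.75, 2.66 and 1.53. Il10 had a log2 fold change of 2.46 (SE 0.46, adjusted p = 0.0392). In the resting list 5 of 24 genes were lower and none higher, with 15 lower and 4 higher adjusted over the list alone. The median was -1.46 (camera adjusted p = 1.49e-05, with an estimated correlation adjusted p = 0.145). With the block 13 of its genes were lower and 2 higher. The 5 were Lef1, Satb1, Foxp1, Actn1 and Atp1b1. Foxp1 had 1330 ± 0.680 CPM in ILT3- and 589 ± 42.2 CPM in ILT3+ cells (SD, n = 3, log2 fold change -1.18, adjusted p = 0.0143). Satb1 and Lef1, both nuclear factors of naive T cells, had log2 fold changes of -1.64 and -1.41.

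**Figure D2:**
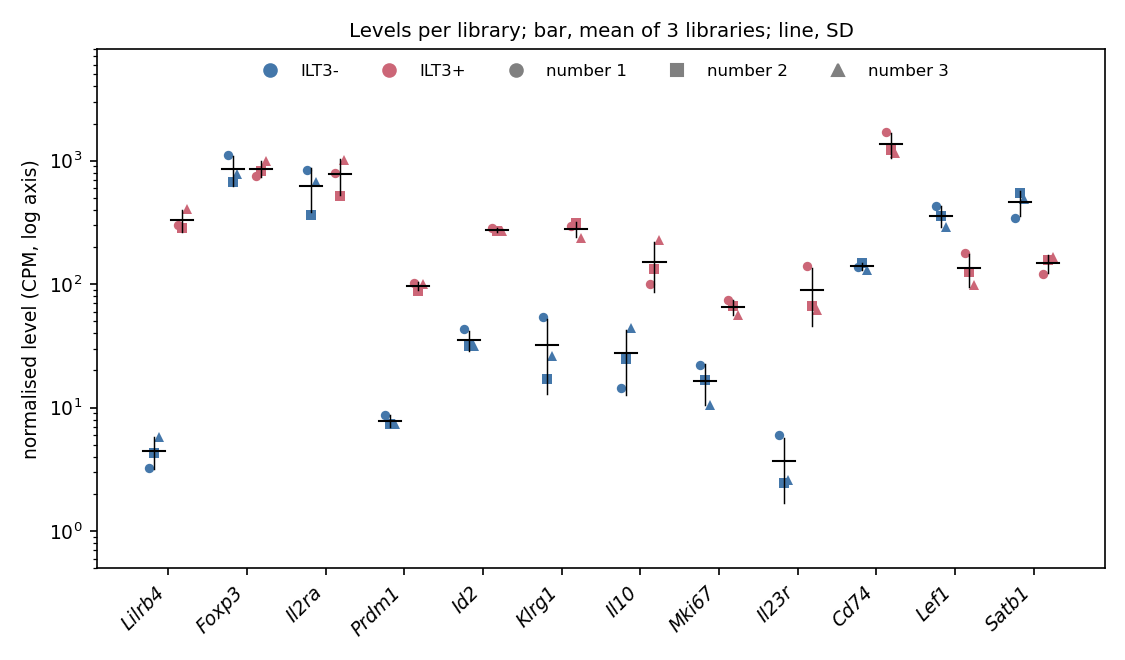
Normalised level (CPM, log axis) of 12 genes in each library, blue for ILT3- and red for ILT3+ cells, with a marker shape for each sample number; the horizontal bar is the mean of 3 libraries and the vertical line the SD. Lilrb4 lay between 284 and 407 CPM in ILT3+ and between 3.24 and 5.81 CPM in ILT3- libraries, while Foxp3 overlapped.

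Proliferation genes were higher in ILT3+ cells. All 36 tested cell cycle genes had a positive log2 fold change, with a median of 1.63 (camera adjusted p = 1.83e-19, with an estimated correlation adjusted p = 0.0307), and 11 were called, 28 adjusted over the list alone. With the block 22 were called. Mki67, the marker Ki-67, was at 65.5 ± 8.96 CPM in ILT3+ and 16.5 ± 5.94 CPM in ILT3- cells (SD, n = 3, adjusted p = 0.0212). Rrm2, a ribonucleotide reductase subunit, and the spindle genes Tpx2 and Kif11 rose by 1.85, 2.55 and 1.99 on the log2 scale.

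Genes of several helper T cell lists were higher, without a detected rise of the main Th1 and Th2 cytokine genes. Ifng, looked at after the values were seen, had a log2 fold change of -0.80 (SE 1.38, adjusted p = 0.880, edgeR). It was at 27.5, 1.26 and 0.291 CPM in ILT3- samples 1, 2 and 3, and at 7.13, 1.61 and 7.82 CPM in ILT3+ samples 1, 2 and 3. The negative value thus rested on ILT3- sample 1. Il4, Il5 and Il13 had too few reads to be tested. Of 12 tested Th1 genes 8 were higher and none lower (9 adjusted over the list alone), with a median of 2.42 (camera adjusted p = 7.59e-09, with an estimated correlation adjusted p = 0.0689). Cxcr3 rose by 1.49, Il18r1 by 2.96 and Runx3 by 2.98 on the log2 scale, and on exon reads by 1.48, 2.80 and 1.99. Of 12 Th17 genes 6 were higher and none lower (10 adjusted over the list alone and 10 with the block), with a median of 2.89 (adjusted p = 6.70e-12, with an estimated correlation adjusted p = 0.0264). Il23r, a subunit of the IL-23 receptor, was at 90.1 ± 44.4 CPM against 3.69 ± 2.01 CPM (SD, n = 3, adjusted p = 0.00760), and Il1r1 at 48.9 ± 6.69 against 1.15 ± 0.663 CPM (adjusted p = 0.00326). Il17f had 392 reads in ILT3+ and 0 in ILT3- libraries, at least 128-fold higher against a floor of 3 reads over the group. Of 12 Th2 genes 2 were higher and 1 lower, 5 and 1 adjusted over the list alone and 4 and 1 with the block (median 0.94, adjusted p = 0.00150, with an estimated correlation adjusted p = 0.0760). The higher ones were Il1rl1, the IL-33 receptor, and Tnfrsf8, at log2 fold changes of 3.22 and 2.28. Of 13 follicular genes 1, Tox2, was higher, also adjusted over the list alone, at 2.67, and the list was not called (adjusted p = 0.663, with the block 1 higher and 1 lower).

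Receptors and secreted factors moved unevenly. Of 17 co-inhibitory receptors 5 were higher, Lag3, Klrg1, Cd200r1, Cd244 and Lilrb4 itself (7 higher and 1 lower adjusted over the list alone, 9 and 1 with the block). The list's camera adjusted p was 0.000243, with an estimated correlation adjusted p = 0.0689. Both include Lilrb4, the gene of the protein used for sorting, and the list was not tested without it. Cd244 had 1 read in ILT3- and 145 in ILT3+ libraries, a ratio of 142 (exact 95% counting interval 25 to 5630). Of 16 co-stimulatory receptors 2 were higher, Icos and Tnfrsf8 (3 adjusted over the list alone, adjusted p of the list 0.408). Of 17 mediators of suppression 5 were higher, Il10, Ebi3, Fgl2, Lag3 and Furin (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.000864, with an estimated correlation adjusted p = 0.145). Of 30 homing receptors 5 were higher, among them Ccr2, Cxcr3, Cxcr6 and Gpr15 (11 higher and 3 lower adjusted over the list alone, 9 and 3 with the block, adjusted p = 0.000361, with an estimated correlation adjusted p = 0.0911). Of 15 cytotoxic genes 2 were higher, Ccl5 and Klrk1 (3 adjusted over the list alone, 5 with the block, adjusted p = 0.000864, with an estimated correlation adjusted p = 0.0757). Only 6.30% of the reads of Fgl2 and 8.47% of those of Cxcr6 were uniquely placed.

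The metabolic and T cell activation lists were not called. None of 35 nuclear oxidative phosphorylation genes, 20 cholesterol synthesis genes or 13 mitochondrially encoded mRNAs was called by edgeR, DESeq2 or voom, with 0 at an unadjusted p under 0.05 in each list and 0 adjusted over the list alone. The lists had adjusted p of 0.842, 0.826 and 0.183. The mitochondrial list was called, with a negative direction, without ILT3- sample 3 (adjusted p = 0.0465) and without ILT3+ sample 1 (adjusted p = 0.0233). In glycolysis Tpi1 was higher (0.94) and Eno3 lower (-2.33), the same counts adjusted over the list alone, 3 higher and 1 lower with the block, and a list adjusted p of 0.450. The 3 subunits of protein kinase CK2, Csnk2a1, Csnk2a2 and Csnk2b, had log2 fold changes of -0.13, 0.07 and 0.16 (0 at an unadjusted p under 0.05 and 0 by DESeq2, list adjusted p = 0.842), with the sign of Csnk2a2 changing between alternatives. Of 25 T cell receptor activation genes 2 were higher, Batf and Cd83 (2 higher and 3 lower adjusted over the list alone, 4 and 6 with the block, list adjusted p = 0.491). None of 25 immediate early and heat shock genes was called by edgeR, with 4 at an unadjusted p under 0.05, 1 called by DESeq2 and 2 lower with the block (adjusted p = 0.842, median -0.06 and mean -0.14 while camera's direction was up). The cholesterol list likewise had a positive median, 0.04, with camera's direction down. No member of the type I interferon list was called by edgeR among 33 tested, with 6 at an unadjusted p under 0.05, 1 adjusted over the list alone, 2 with the block and 3 by DESeq2. Camera called the list higher (median 0.38, adjusted p = 0.0196, with an estimated correlation adjusted p = 0.705). That call was lost without ILT3- sample 2 (adjusted p = 0.268), ILT3- sample 3 (adjusted p = 0.498) or ILT3+ sample 1 (adjusted p = 0.269), and kept without ILT3- sample 1 (4.34e-07), ILT3+ sample 2 (0.0123) or ILT3+ sample 3 (0.0164).

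Some markers of other cell types were also higher in ILT3+ libraries. Enough reads for a test were found for 15 of 21 dendritic cell and 18 of 30 monocyte and macrophage genes. The same held for 6 of 17 erythroid and platelet and 5 of 17 NK and innate lymphoid genes. Members with hardly any ILT3- reads passed the filter only through the ILT3+ libraries and could only be higher there. Of 15 tested dendritic cell genes 8 were higher, namely the antigen presentation genes H2-Aa, H2-Ab1, H2-Eb1, Cd74 and Ciita and the genes Batf3, Ccl22 and Fscn1 (8 adjusted over the list alone, median 3.29, camera adjusted p = 4.09e-12, with an estimated correlation adjusted p = 0.0307). Cd74, the MHC class II invariant chain, was at 1368 ± 311 CPM in ILT3+ and 139 ± 9.62 CPM in ILT3- cells (SD, n = 3, adjusted p = 0.000946). Of 18 monocyte and macrophage genes Tyrobp and Fcer1g were higher, both signalling adaptors (8 higher adjusted over the list alone, 8 with the block, adjusted p = 5.25e-07, with an estimated correlation adjusted p = 0.290). Fcer1g was at 145 ± 6.74 against 6.26 ± 0.917 CPM (SD, n = 3, adjusted p = 0.000327). Tyrobp was at 47.8, 13.8 and 9.25 CPM in ILT3+ samples 1, 2 and 3. The macrophage gene Csf1r had 2833 reads in ILT3+ sample 1 and 28 and 5 in ILT3+ samples 2 and 3. Of 6 erythroid and platelet genes 3 were higher, Hba-a1, Hba-a2 and Car2 (5 adjusted over the list alone, 5 with the block, adjusted p = 1.49e-05, with an estimated correlation adjusted p = 0.145), and Hba-a2 had 74.3, 13.1 and 14.8 CPM in the 3 ILT3+ and 1.56, 0.393 and 0.509 CPM in the 3 ILT3- libraries. Of 5 tested NK and innate lymphoid genes 3 were higher, Il1rl1, Kit and Tyrobp (3 adjusted over the list alone, adjusted p = 2.70e-05, with an estimated correlation adjusted p = 0.0689). Of the 5 tested genes 4 were also in other lists. The B cell list (1 of 18 higher, Mef2c, 3 adjusted over the list alone, 3 with the block, adjusted p = 0.000139, with an estimated correlation adjusted p = 0.142) and the plasma cell list (1 of 10 higher, Prdm1, 3 adjusted over the list alone, 2 with the block, adjusted p = 0.000996, with an estimated correlation adjusted p = 0.0760) were called. The plasmacytoid dendritic cell list was called with no member called by edgeR (9 tested, 6 at an unadjusted p under 0.05, 2 by DESeq2, 3 higher and 1 lower adjusted over the list alone, 2 and 1 with the block, adjusted p = 0.0138, with an estimated correlation adjusted p = 0.135), and not without ILT3- sample 2 (adjusted p = 0.0540). The CD8 T cell, mast cell and basophil, and sex chromosome lists were not called (adjusted p = 0.453, 0.450 and 0.753). The neutrophil and stromal lists had 2 tested members each and were not tested.

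**Figure D3:**
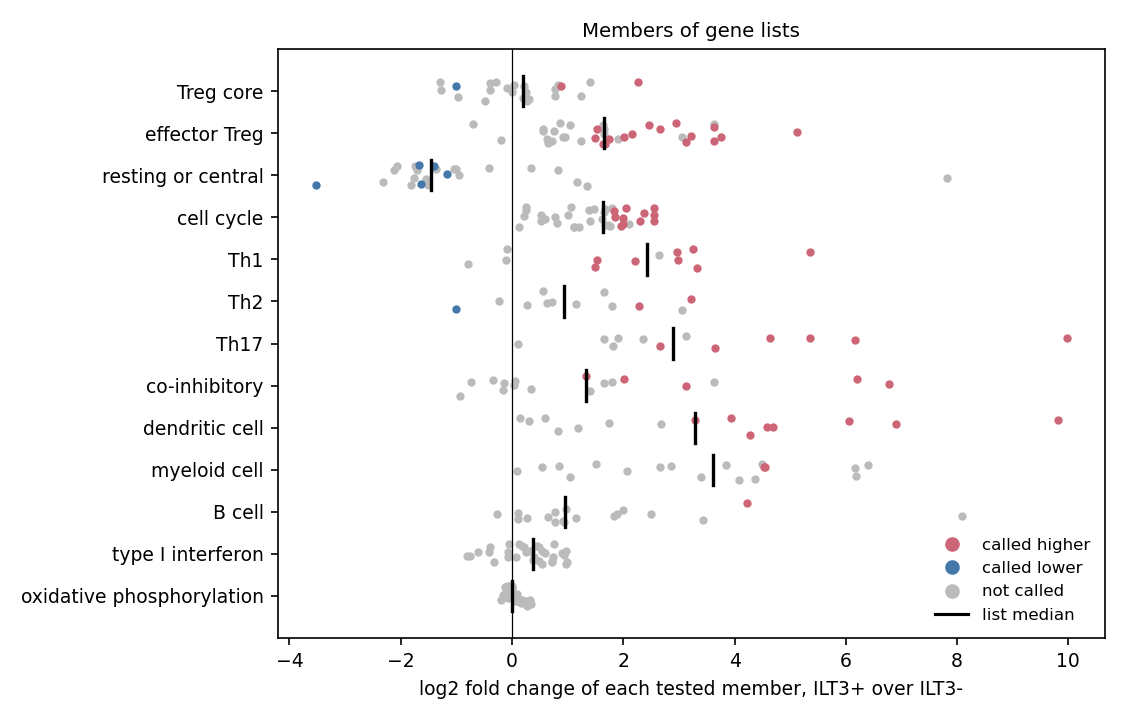
Log2 fold change, ILT3+ over ILT3-, of each tested member of 13 lists, with called members in red (higher) or blue (lower), other members in grey, and the list median as a black bar. The medians of the effector Treg, cell cycle and Th17 lists lie at 1.65, 1.63 and 2.89, and that of the resting list at -1.46.

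Among called genes of at least 10 CPM, with predicted genes and Rik clones left out, the largest rises besides Lilrb4 and Hba-a2 included those of Chad, Upp1, Stab1, Ablim3, Serinc2, Dscaml1 and Abi3bp. Chad, a cartilage matrix protein gene, had 2 reads in ILT3- and 1138 in ILT3+ libraries, a ratio of 556 (exact 95% counting interval 154 to 4600), with 15.3% of its reads uniquely placed. Upp1, the uridine phosphorylase, was at 67.3 ± 32.3 against 0.498 ± 0.862 CPM, and Stab1, a scavenger receptor gene, at 21.7 ± 4.70 against 0.206 ± 0.241 CPM (SD, n = 3). The largest falls among the same genes were those of Atp1b1, Tubb2b, St8sia6, Trpm1, Colq, Eno3, Lad1, Chchd10, St8sia1 and Pla2g4f, with log2 fold changes from -3.53 to -2.14. St8sia1 and St8sia6, both sialyltransferases, were at 100 ± 30.1 and 86.1 ± 38.1 CPM in ILT3- and 22.4 ± 1.41 and 15.2 ± 7.21 CPM in ILT3+ cells (SD, n = 3, adjusted p = 0.0105 and 0.0397). Atp1b1, a sodium pump subunit, was at 19.4 ± 9.95 against 1.66 ± 0.479 CPM (adjusted p = 0.0183). Of the 66 named genes that were called, 7 were called in every alternative that tested them, namely Lilrb4, Prdm1, Id2, Il1r1, Fcer1g, Cd74 and Kit. The others lost their call in at least 1, and 55 did so without ILT3- sample 3.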

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

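The settings without both number 1 libraries, with library size only, with exon reads plus the block and with lists on exon reads were chosen after the data were seen. The ILT3 gene was called in every alternative (log2 fold change 6.03 to 7.44), and no gene among the 316 changed sign in any of them. The count was 951 with DESeq2 (697 higher, 254 lower), which made 35 false calls in 172 on data simulated with edgeR's dispersions. With the replicate block it was 932 (573 and 359), with exon reads plus the replicate block 700 (415 and 285), and without both number 1 libraries 786 (625 and 161). It was 204 (177 and 27) on unique exon reads, 236 (29 lower) on exon reads, 195 (177 and 18) against a 1.5-fold minimum and 51 (48 and 3) at an adjusted p of 0.01. Leaving out 1 library gave 31 to 322 genes, 27 to 274 higher and 1 to 48 lower: 67 without ILT3- sample 2, 31 without ILT3- sample 3, 53 without ILT3+ sample 2 and 57 without ILT3+ sample 3. At the same number of libraries it was 322 without ILT3- sample 1 and 257 without ILT3+ sample 1, so the low counts came only where a number 2 or 3 library was left out. The cause was not tested. RLE factors (314), upper quartile factors (314), library size only (365), voom (316), no filter (395), a stricter filter (318) and unique gene reads (340) stayed within 1.5 times. The share called higher was 61.5% with the block against 85.1% without. Of 19 lists 4 were called with an estimated correlation, and 16 to 19 of the same 32 tested lists with 1 library left out. The replicate block changed the call of no list; among named genes it ended 0 calls and added 23.

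Direction changed 37 times among named genes, each time in genes not called in either fit, and the cause was not tested. Foxp3 (0.00) was 0.35 without both number 1 libraries, 0.11 with library size only, 0.022 with voom, 0.044 without a filter, 0.024 with the block, 0.021 with exon reads plus the block, 0.0066 with upper quartile factors, and -0.14 to 0.23 with 1 library left out. Irf4 was 0.027 with voom, 0.039 with the block and 0.12 with exon reads plus the block. Ctss was -0.16 without both number 1 libraries and -0.028 with exon reads plus the block. Without both number 1 libraries Cd7 was -0.31, Csnk2a2 -0.11, Eif2s3y 0.13, Srebf2 0.052 and Xist -0.16. With 1 library left out, Cd37 ranged from -0.19 to 0.55, Cd7 from -2.32 to 3.55, Csnk2a2 from -0.24 to 0.47, Ctss from -0.41 to 0.31, Gzmm from -1.49 to 0.35, Irf4 from -0.80 to 0.48, Irg1 from -1.05 to 1.67, Itgb8 from -0.10 to 0.74, Kdm5d from -0.12 to 0.27, Mmp9 from -0.37 to 7.38 and Xbp1 from -0.078 to 0.53. The lists that changed direction without being called were cholesterol (adjusted p = 0.219 without both number 1 libraries, 0.0505 to 0.686 with 1 library left out), CK2 (0.706, and 0.595 to 0.955), immediate early (0.922 with a stricter filter, 0.921 on exon reads, and 0.0603 to 0.929), oxidative phosphorylation (0.540 to 0.972) and follicular (0.544 to 0.921). The interferon list was not called on exon reads (adjusted p = 0.0524) or by fry (0.415), the plasmacytoid list not with a stricter filter (0.0541), and the mast cell list was called on exon reads (0.0378).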

Other observations

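All tests of explanations in this part, with their bounds and the gene sets behind them, were chosen after the results had been seen.

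Of 12 genes for receptor adaptors and kinases, picked after their values were seen and not tested as a set, 6 were called higher in ILT3+ cells and none lower, namely the adaptors Fcer1g, Tyrobp and Clnk, the phospholipase Plcg2 and the kinases Lyn and Tec. Lyn was at 92.9 ± 3.81 CPM in ILT3+ and 15.9 ± 4.76 CPM in ILT3- cells, Plcg2 at 73.4 ± 9.26 against 3.69 ± 2.48 CPM and Clnk at 124 ± 15.2 against 6.13 ± 1.41 CPM (SD, n = 3). With the block the same 6 were called. On exon reads Lyn, Clnk and Tec were not called (adjusted p = 0.157, 0.0537 and 0.0555, edgeR). Their log2 fold changes were not smaller there, at 3.04, 5.56 and 2.12 against 2.55, 4.34 and 2.12, but the SE was larger (0.87, 1.13 and 0.44 against 0.26, 0.25 and 0.22). The kinases Syk and Btk had log2 fold changes of 2.37 and 1.38 and were not called (adjusted p = 0.276 and 0.460). The T cell kinases Lck, Fyn and Zap70 had log2 fold changes of -0.38, -0.31 and -0.18 and were not called.

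Chemokine and cytokine genes, and genes of IL-1 family receptors and the IL-1 receptor antagonist, were picked in the same way, without a set test. Of 10 chemokine genes 4 were called higher, Cx3cl1 (86.6 ± 24.4 against 2.78 ± 0.539 CPM), Cxcl10, Ccl5 and Ccl22, the last with 341 reads in ILT3+ and 0 in ILT3- libraries, at least 111-fold higher, while Ccl1, Ccl3, Ccl4, Ccl20, Cxcl16 and Xcl1 were not called. With the block Ccl3 and Ccl20 were called higher too (adjusted p = 0.0208 and 0.00761). Of 9 tested cytokine genes 5 were called higher, Il10, Ebi3, Penk, Il22 and Il17f, and Ifng, Il21, Areg and Tgfb1 were not (log2 fold changes -0.80, 2.35, 0.72 and -0.32), with the same 5 called with the block. Il10 was not called on exon reads (adjusted p = 0.111), where its log2 fold change was 3.11 (SE 0.80) against 2.46 (SE 0.46). Penk, the proenkephalin gene, was at 443 ± 52.5 against 59.4 ± 12.5 CPM (SD, n = 3, adjusted p = 0.00187, edgeR). Of 7 genes of IL-1 family receptors and the antagonist (Il1rn), 4 were called higher, Il1r1, Il1rl1, Il18r1 and Il18rap. Il1r2, Il1rap and Il1rn were not, although edgeR with the block called Il1r2 (adjusted p = 0.00218). Of the Y-linked genes and Xist none was called.

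Of 11 MHC class II genes 7 were called higher in ILT3+ cells, 8 with the block, which added H2-DMb2 (adjusted p = 0.00528), and 3 sources were weighed. Myeloid RNA in ILT3+ sample 1 alone is argued against, because all 7 genes were still called without both number 1 libraries. B cells stay open because their genes disagree. The summed CPM of Ms4a1, Cd79a and Cd79b rose by at most 2.42% of the rise of H2-Aa, H2-Ab1 and H2-Eb1 in any number pair. Igkc rose by 4.67%, 0.293% and 13.4% of it in the pairs 1, 2 and 3, while Ighm rose by 63.4%, 88.2% and 96.9%. Ighm already stood at 579 ± 350 CPM in ILT3- cells (SD, n = 3) and was not called (log2 fold change 0.97, adjusted p = 0.407, with the block 0.00746). Ighm and Igkc were added after their values were seen. Dendritic cells or macrophages stay open too, because their genes disagree. Of 21 of their genes 14 were tested, with 3 called higher (Batf3, Fscn1 and Ccl22) and 0 lower, and 7 higher with the block. Clec9a and Cd209a had 0 reads in every ILT3+ library. Itgax had 49, 0 and 1 reads in ILT3+ samples 1, 2 and 3, and Flt3 had a log2 fold change of 0.15. Cst3, Ctss and Lyz2 rose by 18.3%, -3.17% and 7.08% of the MHC rise in the pairs 1, 2 and 3, where Ctss already stood at 300 CPM in ILT3- cells. How many cells of these other types passed the CD4+CD25+ gate was not measured. Sorting on surface ILT3 would place antigen-presenting cells that carry it in the ILT3+ group. Transcription in the ILT3+ T cells themselves is the biological alternative and was not tested.

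Of 21 tested type 17 and innate lymphoid genes 10 were called higher in ILT3+ cells, 15 with the block (the 10 include Il23r, Il22, Il17f, Il17re, Il1r1, Kit, Id2, Tmem176b and Klrb1b). Reads of introns, overlapping genes or other copies are argued against, since all 10 were at least 4-fold higher on uniquely placed exon reads, 9 of them called, with Tmem176b at an adjusted p of 0.0507. Innate lymphoid cells without a T cell receptor may contribute, since some carry CD4 and CD25 and would pass the gate. The summed CPM of Trac, Trbc1 and Trbc2 had log2 ratios of -0.47, -0.59 and -0.72 in the 3 pairs (mean -0.59). By gene, the log2 fold change was -0.19 for Trac, -0.73 for Trbc1 and -0.64 for Trbc2. The summed CPM of Cd3e, Cd3d, Cd3g and Cd247 fell less, with log2 ratios of -0.27, -0.23 and -0.34 in the pairs 1, 2 and 3. Of Trac, Trbc1 and Trbc2 none was called without the block, and Trbc1 and Trbc2 were called lower with it (adjusted p = 0.0121 and 0.0123, edgeR). Foxp3 was lower in pair 1 (-0.57) and higher in pairs 2 and 3 (0.28 and 0.35). A share of innate lymphoid cells therefore cannot be told apart from expression in the sorted T cells themselves, Tregs or other CD4+CD25+ T cells. Neither source was tested.

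More genes were called higher than lower. The choice among the scalings tried was not the source. The share of called genes that were higher was 85.4% to 89.0% with RLE factors, upper quartile factors and library size only, against 85.1% with TMM. These scalings barely differed, with a median log2 fold change over tested genes of -0.0257, -0.00751 and 0.0621, against -0.0217 with TMM. They therefore cannot decide whether a larger scaling error played a part. With the replicate block the share was 61.5%, as both directions gained calls, from 269 to 573 higher and from 47 to 359 lower.

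The 6 samples can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05. The real split was 1 of 10 with as many genes called, with 316 against at most 0 in the other splits, and likewise for genes higher (269 against 0), genes lower (47 against 0) and lists called (19 against 13). Of the other splits, 3 also parted all 3 number pairs, and these called 0 genes and at most 9 lists. In edgeR the other splits had 106 to 1316 genes at an unadjusted p under 0.05, against 1889 in the real one. The split with 13 lists put both number 1 libraries on the same side, so it is not free of the sample number difference. With up to 9 lists called where all pairs were parted, a list call at the preset correlation is still weak evidence by itself.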
